A study of Mus musculus with 6 samples.

How the data were processed

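Epithelial cells from the small intestine of C57BL/6JRj mice were freed by EDTA and trypsin digestion and sorted as EpCam-positive, CD45-negative cells, per the labels. CD45 is the surface protein of leukocytes, encoded by Ptprc, and EpCam is an epithelial adhesion molecule. The series design names the proximal small intestine of 3 young and 3 aged mice, so the 6 libraries were taken as 1 per mouse. Poly(A) RNA was made into libraries with a stranded kit, per the labels' protocols. The labels give no batch, sex or replicate number. Replicates were numbered in the order of the records, and no pairing of young with aged libraries is given. The mitochondrial share of counts fell with the number in both groups. It was 3.69, 2.07 and 1.48% in young and 2.88, 2.04 and 1.54% in aged libraries. A pairing by number thus cannot be excluded, and no paired or blocked fit was run. The organoid, single-cell and chromatin data of the same study were not used here.

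The deposited table holds raw counts per gene for 46078 Ensembl genes and was not normalised by the authors, as its whole numbers and unequal column totals show. The submitters' processing notes name GRCm38 and the tools FastQC 0.11.8, cutadapt 2.5, Trim Galore 0.6.4, STAR, HISAT2 2.1.0, Picard, SAMtools 1.9, featureCounts 1.6.4, StringTie 2.0, deepTools 3.3.1, MultiQC 1.7 and DESeq2 1.28.1, without their order or role. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or lie antisense to one another, and members of near-identical families such as the defensins, the Gbp and Irg GTPases and the ribosomal protein copies, have uncertain counts. Positions are from GENCODE M21 on GRCm38, 1-based. Of the gene IDs, 45229 were found there and 849 were not, and the latter held 0.056% of all counts.

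Total counts ran from 41479573 to 58989166 per library, a ratio of 1.42. A gene with 0 counts in a library could lie at up to 3 counts, which is between 0.0509 and 0.0723 CPM (counts scaled to a common library total) over the 6 libraries. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No library pair agreed within sampling noise: the smallest chi-square per gene between libraries of a group was 27.2, where sampling noise alone gives about 1.

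Genes were kept by the filterByExpr rule of edgeR 4.0.16 (minimum count 10), which left 14923 genes, and scaled with TMM factors. The main test was edgeR's quasi-likelihood test with robust estimation, in a model with age as its term and all 6 libraries (R 4.3.3). Adjusted p-values are Benjamini-Hochberg values, and 0.05 was the threshold. The standard error of a log2 fold change was derived as its size over the square root of the F statistic. CPM values use the TMM factors and are given as mean ± SD of 3 libraries. Fixed gene lists with at least 4 tested members were compared with all other genes by camera in limma 3.58.1, on voom values with a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry. Of 40 lists, 34 were tested. Principal components used log2 CPM with a prior count of 2. The list of immunoglobulin segments was defined by a symbol pattern, and its only tested member was the helicase gene Ighmbp2, which is not a segment.

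Genes were named by a rule. It took the 10 most raised and the 10 most lowered called genes with a mean of at least 5 CPM and no overlap between the age groups, without Gm, Rik and unnamed symbols. It also took up to 4 called members per list, or the 2 most abundant members where none was called, and 7 genes whatever their result (Cdkn2a, Cdkn1a, Lgr5, Olfm4, Cd74, Ptprc and Epcam). Groups, tests, lists, this rule and the alternatives were set before the data were examined. The alternatives were DESeq2 1.42.0, other scaling factors, other filters, limma-voom, non-robust estimation, a test against a fold of 1.5, removal of genes of other cell types, 1 surrogate variable (sva 3.50.0) and leaving out each library.

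The tests were tried on simulated counts for 14923 genes with the real means, library sizes and dispersions, of which 200 were changed. For aged against young, the edgeR test recovered 26 of 50 genes changed 1.5-fold, 44 of 50 changed 2-fold and 47 of 50 changed 4-fold, and 6.2% of its 176 calls were false. In the same simulation 14.7% of the 197 DESeq2 calls were false. All 3 list tests called the 4 moved lists of 40 and no other. Genes were simulated independently of one another, so this could not show false list calls that arise when members of a list move together. Differences that many genes of a library share were not simulated either. The false shares of gene calls therefore need not hold for the real libraries.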

Results

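RNA was sequenced from sorted epithelial cells of the small intestine of 3 young mice (2 to 3 months old) and 3 aged mice (20 to 22 months old). The values are raw counts per gene. The young libraries held 44511852, 58989166 and 41479573 counts and the aged libraries 47841455, 45328055 and 55670388. Epcam, the sorting marker, stood at 1656 ± 18.2 CPM in young and 1510 ± 11.3 CPM in aged libraries (SD, n = 3 each), and Ptprc, which encodes the leukocyte marker sorted against, at 0.235 ± 0.0611 and 0.230 ± 0.0404 CPM. The single comparison of the design asks how the gut epithelium of aged mice differs from that of young mice, with inflammation named in the title of the series.

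In the epithelium of aged mice 4 of 7 MHC class II, 4 of 21 MHC class I and 13 of 23 interferon-gamma response genes rose, and 4 of 16 Paneth, 2 of 17 goblet and 3 of 25 enteroendocrine genes fell. Camera called all 6 lists with a preset correlation, and with an estimated correlation none was called (adjusted p = 0.350 for the first 5 and 0.700 for the enteroendocrine list). Of 14923 genes tested, 93 were higher and 117 lower in aged libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 1377 genes had an unadjusted p below 0.05. The median log2 fold change was 1.33 among the genes called higher and -1.55 among those called lower. The lower genes were mostly of low abundance, with a median of 3.06 CPM against 13.4 CPM for the higher genes. The first principal component held 45.6% of the variance and placed the young libraries between -31.3 and -11.1 and the aged libraries between 9.2 and 31.7. The second held 22.4% and placed young replicate 2 at -34.8 and aged replicate 3 at 21.8, apart from the others. The groups did not overlap in 2058 genes (13.8%), where chance gives 10%. Leaving out 1 library moved the count of higher genes between 35 (without aged replicate 2) and 135 (without aged replicate 3), and that of lower genes between 30 (without aged replicate 1) and 135 (without aged replicate 3).

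Of 7 tested genes of MHC class II presentation, which displays peptides to helper T cells, 4 rose in aged mice and the other 3 did not pass the test over all genes; adjusted over the list alone, all 7 did. Ciita (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418, GRCm38), the transactivator of these genes, rose from 4.27 ± 1.31 to 61.3 ± 23.9 CPM, a log2 fold change of 3.83 ± 0.36 (SE, adjusted p = 0.00656). H2-Eb1 rose from 8.43 ± 4.07 to 294.7 ± 166.5 CPM (adjusted p = 0.0412). H2-DMa, which helps to load peptides, rose 7.76-fold (adjusted p = 0.0274), and its partner H2-DMb1 rose 21.1-fold (adjusted p = 0.0467). Cd74, the invariant chain, stood at 62.8 ± 34.8 CPM in young and 1802 ± 1002 CPM in aged libraries, a log2 fold change of 4.84 ± 0.74 that missed the threshold (adjusted p = 0.0593). Its aged libraries held 2186, 2555 and 663.8 CPM, each above the 3 young ones, and without aged replicate 3 the adjusted p was 0.0169 (range over the alternatives 4.9e-11 to 0.32). The median log2 fold change of the list was 4.43. The list was called higher by camera (adjusted p = 8.37e-16), a call lost at adjusted p = 0.350 with an estimated correlation, and fry gave an adjusted p of 0.0917. H2-Eb1 and H2-DMb1 lost their calls in 5 of the 6 fits without 1 library, all but that without aged replicate 3, and H2-DMa in 4. Ciita lost its call without young replicate 3 (adjusted p = 0.0577).

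Of 21 tested MHC class I presentation genes, which serve display to cytotoxic T cells, 4 rose, 17 did not pass, and 15 were higher when adjusted over the list alone. The peptide transporter genes Tap1 (55.8 ± 4.78 to 164.3 ± 35.2 CPM, adjusted p = 0.00331) and Tap2 (2.28-fold, adjusted p = 0.0151) rose, as did the immunoproteasome subunit Psmb9 (2.52-fold, adjusted p = 0.0432) and Nlrc5, the class I transactivator (2.03 ± 1.18 to 31.4 ± 15.9 CPM, adjusted p = 0.0421). The list had a median log2 fold change of 0.71, or 0.45 with 1 surrogate variable (camera adjusted p = 1.54e-17; adjusted p = 0.350 with an estimated correlation; fry adjusted p = 0.211). Tap2, Psmb9 and Nlrc5 lost their calls in 5 of the 6 fits without 1 library, all but that without aged replicate 3, with adjusted p up to 0.0768, 0.202 and 0.256.

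Of 23 tested interferon-gamma response genes 13 rose, and 22 were higher when adjusted over the list alone. Among these, the GTPase genes of cell-autonomous defence Igtp (7.28 ± 1.19 to 46.1 ± 11.9 CPM, adjusted p = 0.00104), Irgm2 (6.11 ± 1.33 to 31.9 ± 8.12 CPM, adjusted p = 0.00266), Ifi47 (16.0 ± 0.967 to 35.8 ± 6.77 CPM, adjusted p = 0.00656) and Tgtp2 (0.120 ± 0.0842 to 2.04 ± 0.637 CPM, adjusted p = 0.00656) rose. Igtp and Irgm2 overlap on chromosome 11 (58199556 to 58207591 and 58199618 to 58222782), so their counts are not independent. The median log2 fold change of the list was 1.72 (camera adjusted p = 2.79e-31; adjusted p = 0.350 with an estimated correlation; fry adjusted p = 0.0430). The type I interferon list had a median of 0.24 with 0 of 27 members called, and 0 were called when adjusted over the list alone (camera adjusted p = 0.00528; adjusted p = 0.759 with an estimated correlation). Its most abundant members Ifi27l2b and Irf9 had log2 fold changes of -0.13 and 0.36. The difference between these lists was not tested. The inflammatory cytokine and NF-kB list had a median of 0.18, with 0 of 26 members called and 3 higher when adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.759 with an estimated correlation). Camera lost the type I call without young replicate 1, young replicate 3 or aged replicate 2 (adjusted p up to 0.111), and the NF-kB call without young replicate 2, aged replicate 1 or aged replicate 2 (up to 0.226). The type I median was 0.12 without aged replicate 2, 0.13 without young replicate 3, 0.43 without aged replicate 3 and 0.49 without young replicate 2. The NF-kB median was 0.05 without aged replicate 1, 0.06 without aged replicate 2 and 0.31 without aged replicate 3. With 1 surrogate variable both calls were lost (medians 0.08 and 0.07, adjusted p = 0.395 and 0.0823).

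**Figure D1:**
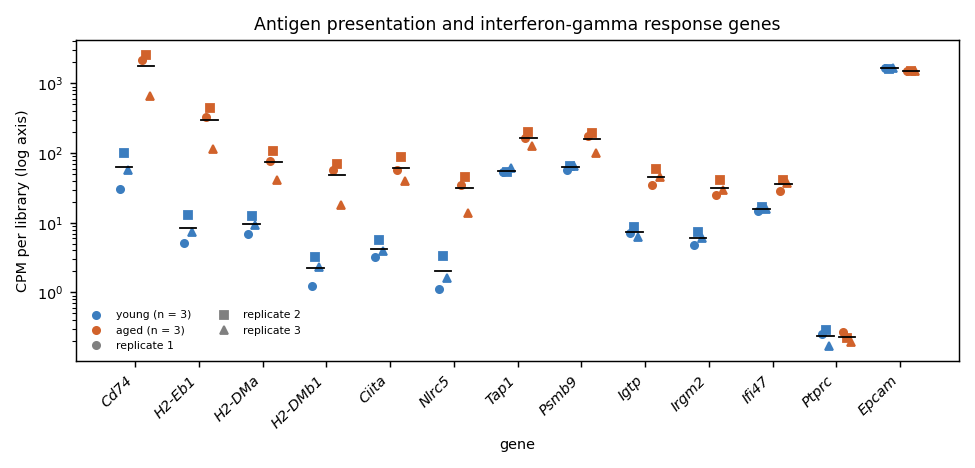
Scaled counts (CPM, log axis) of antigen presentation and interferon-gamma response genes, with Ptprc and Epcam, in each of the 3 young and 3 aged libraries; points are libraries and bars are group means. Cd74 lay between 31.0 and 100 CPM in young and between 663.8 and 2555 CPM in aged libraries, while Ptprc stayed near 0.23 CPM in both groups.

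Markers of other cell types were measured beside these groups. The list for macrophages, dendritic cells and neutrophils had a median log2 fold change of 0.51 (camera adjusted p = 0.0189; adjusted p = 0.350 with an estimated correlation; fry adjusted p = 0.0430). Its call was lost without young replicate 2 or aged replicate 2 (adjusted p up to 0.0709), with the filter of 1 CPM in 3 libraries (0.0520) and with 1 surrogate variable (0.0816), and its median was 0.22 without young replicate 3 and 0.22 without a filter. Of its 7 tested members only Itgam, an integrin subunit, rose, from 12.6 ± 0.681 to 21.6 ± 1.18 CPM (adjusted p = 0.00726). In the T lymphocyte list, which was not called (median 0.27, camera adjusted p = 0.484), Itgae, the integrin subunit CD103, rose from 1.16 ± 0.214 to 3.40 ± 0.582 CPM (adjusted p = 0.0129); the other 10 tested members did not pass. Without aged replicate 2 this list was called higher (median 0.50, adjusted p = 0.00228), and without aged replicate 1 its median was -0.20; it was 0.17, 0.12 and 0.13 without young replicate 1, young replicate 2 and aged replicate 3. Itgae lost its call without young replicate 3 or aged replicate 1 (adjusted p up to 0.0749). Lists for fibroblasts and smooth muscle (median -0.19) and enteric neurons and glia (-0.04) were not called (camera adjusted p = 0.632 and 0.557), though the latter was called lower without young replicate 2 (median -0.32, adjusted p = 0.0347) and had a median of 0.12 without young replicate 3, 0.10 without young replicate 1, -0.32 without aged replicate 1, -0.0025 without aged replicate 2 and -0.26 without aged replicate 3. The fibroblast median was -0.01 without young replicate 3 and -0.78 without a filter (camera adjusted p = 0.0528). With 1 surrogate variable it was -0.06, and the median of the neuron and glia list was 0.27. Lists for B and plasma cells, mast cells, endothelium, erythroid and pancreatic acinar cells had at most 3 tested members and 0 calls over all genes. Adjusted over the list alone, 1 acinar gene was higher. The sex-linked list was not called either (median -0.08, camera adjusted p = 0.735; -0.02 without young replicate 1 and -0.0081 without aged replicate 1), and the Y-linked Eif2s3y stood at 38.3 ± 1.91 and 41.1 ± 5.75 CPM. Over the 6 libraries Eif2s3y lay between 37.2 and 47.7 CPM and the Y-linked Kdm5d between 33.8 and 42.5 CPM, so all 6 mice were read as male.

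Of 16 tested Paneth cell genes, which encode antimicrobial products of the crypt base, 4 fell in aged mice, 12 did not pass, and 10 were lower when adjusted over the list alone. The defensin genes Defa3 (23.3 ± 5.80 to 8.22 ± 0.900 CPM, adjusted p = 0.00656), Defa26 (61.1 ± 15.9 to 28.0 ± 2.90 CPM, adjusted p = 0.0220) and Defa17 (243.1 ± 73.7 to 111.7 ± 0.344 CPM, adjusted p = 0.0373) fell, as did the pentraxin Mptx1 (3.90 ± 0.656 to 0.769 ± 0.485 CPM, adjusted p = 0.0498). Defensin copies are near-identical, so the counts of single copies are uncertain. The median log2 fold change was -0.88 (camera adjusted p = 8.51e-15; adjusted p = 0.350 with an estimated correlation; fry adjusted p = 0.251). Defa26 and Defa17 lost their calls without young replicate 1 or any 1 aged library, with adjusted p up to 0.118 and 0.141, and Mptx1 in all such fits but that without aged replicate 1 (up to 0.183).

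All 17 tested goblet cell genes had log2 fold changes below 0, and 2 of them fell. Tff3, a trefoil peptide of mucus, fell from 1755 ± 307.3 to 1105 ± 114.5 CPM (adjusted p = 0.0498) and Klk1 from 102.3 ± 12.2 to 71.4 ± 4.98 CPM (adjusted p = 0.0412). Adjusted over the list alone, 7 were lower. The median was -0.42 (camera adjusted p = 8.05e-12; adjusted p = 0.350 with an estimated correlation; fry adjusted p = 0.266), and -0.27 without young replicate 3. Of 25 tested enteroendocrine genes 3 fell: Gip, an incretin hormone (242.9 ± 9.73 to 175.9 ± 15.3 CPM, adjusted p = 0.0285), Sst, which encodes somatostatin (52.0 ± 7.01 to 27.3 ± 6.53 CPM, adjusted p = 0.0432), and the granule protein gene Scg3 (8.56 ± 1.47 to 3.66 ± 0.416 CPM, adjusted p = 0.0101). The median of this list was -0.08 and 4 were lower when adjusted over the list alone (camera adjusted p = 0.00264; adjusted p = 0.700 with an estimated correlation). Its call was lost without young replicate 3 (adjusted p = 0.178), and its median was -0.15 without young replicate 1, -0.14 without young replicate 2 or aged replicate 3, and -0.17 without aged replicate 1. Tff3 and Sst lost their calls in 5 of the 6 fits without 1 library, Klk1 and Gip in 4 and Scg3 in 2, with adjusted p up to 0.171, 0.174, 0.191, 0.125 and 0.0697.

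Stem cell and dividing cell genes showed no called member. The intestinal stem cell list had a median log2 fold change of -0.04 over 24 genes (camera adjusted p = 0.0924), with 1 gene lower when adjusted over the list alone. Without young replicate 2 this list was called lower (median -0.11, camera adjusted p = 0.000566), and the median was -0.09 without aged replicate 1 and -0.0024 without young replicate 1. Lgr5, a marker of crypt base stem cells, stood at 59.7 ± 12.6 and 51.1 ± 2.74 CPM (adjusted p = 0.770), and was lower without young replicate 2 (log2 fold change -0.40, adjusted p = 0.0474; range over the alternatives 0.0474 to 0.9995). Olfm4 stood at 4276 ± 497.2 and 3970 ± 417.0 CPM (adjusted p = 0.879). The proliferation list had a median of 0.08 over 31 genes, with 28 above 0 (camera adjusted p = 0.00876; adjusted p = 0.759 with an estimated correlation). Its call was lost without young replicate 3, aged replicate 2 or aged replicate 3 (adjusted p up to 0.664). Its median was 0.01 without aged replicate 2, 0.03 without young replicate 3, 0.16 without aged replicate 1 and 0.18 without young replicate 2. With 1 surrogate variable the call was lost as well (0.02, adjusted p = 0.510). The Wnt target (-0.02), Notch (-0.09), tuft cell (-0.18) and senescence and p53 (0.01) lists were not called. The Notch median was -0.04 without young replicate 2. The tuft cell list was called lower without aged replicate 1 (median -0.33, adjusted p = 0.00337) and with the filter of 1 CPM in 3 libraries (-0.24, adjusted p = 0.0299), and its median was -0.02 without aged replicate 3. The senescence and p53 list was called lower with 1 surrogate variable (-0.05, adjusted p = 0.0234), and the sign of its median and of the Wnt median varied over the fits without 1 library. Cdkn1a, a cell cycle inhibitor, stood at 118.1 ± 13.7 and 104.0 ± 6.28 CPM (adjusted p = 0.660). Cdkn2a, another, was too low to test, with 5 counts over the young and 10 over the aged libraries.

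The medians of the metabolic and regional lists lay between -0.32 (ileal) and 0.09 (cholesterol synthesis). Cholesterol synthesis genes (median 0.09, adjusted p = 0.0164 by camera in limma) were called higher. Absorptive enterocyte (-0.14, adjusted p = 0.0189), fatty acid oxidation (-0.08, adjusted p = 0.0189), iron handling (-0.09, adjusted p = 0.0164), ileal (-0.32, adjusted p = 0.0381) and duodenal genes (-0.14, adjusted p = 0.0381) were called lower. With an estimated correlation their adjusted p-values were 0.759, 0.759, 0.759, 0.658, 0.350 and 0.671. Among their members only Gip was called, and adjusted over the list alone 2 genes each were lower in the iron, ileal and duodenal lists and 0 in the others. Each of these calls was lost without 1 or more single libraries, aged replicate 2 in every case, and with 1 surrogate variable (adjusted p between 0.0517 and 0.857), where the enterocyte, fatty acid oxidation, cholesterol, iron and duodenal medians were -0.03, 0.07, 0.05, -0.0083 and -0.09. Without a filter the duodenal median was -0.08. The enterocyte median was 0.03 without young replicate 1, 0.02 without aged replicate 2, -0.25 without young replicate 2 and -0.26 without aged replicate 3. Without aged replicate 2 the fatty acid oxidation, iron, ileal and duodenal medians were -0.0013, -0.04, -0.15 and -0.08. Without young replicate 2 the fatty acid oxidation, ileal and duodenal medians were -0.19, -0.15 and -0.27, and the cholesterol median was 0.14. Without young replicate 3 the cholesterol, fatty acid oxidation and duodenal medians were 0.03, -0.04 and -0.07. Without young replicate 1 the fatty acid oxidation and iron medians were -0.05 and -0.02, without aged replicate 3 they were -0.19 and -0.17, and without aged replicate 1 the duodenal median was -0.08. The antimicrobial lectin (-0.17), xenobiotic defence (-0.04), unfolded protein response (0.03), immediate early (0.06), junction (-0.01), oxidative phosphorylation (-0.02), mitochondrially encoded (-0.19), ribosomal protein (0.00) and histone (0.07) lists were not called. Without young replicate 2, camera called the unfolded protein response (0.17) and immediate early (0.17) lists higher, and the antimicrobial (-0.21), xenobiotic (-0.16), oxidative phosphorylation (-0.07) and ribosomal protein (-0.08) lists lower. Without aged replicate 1 it called the xenobiotic (-0.18), mitochondrially encoded (-0.49) and ribosomal protein (-0.04) lists lower, without young replicate 3 the mitochondrially encoded list lower (-0.47), and without aged replicate 2 the immediate early list higher (0.11). The antimicrobial median was -0.08 without aged replicate 2 and -0.09 without young replicate 3. The mitochondrially encoded median was 0.25 without young replicate 1, -0.30 without young replicate 2 and 0.02 without aged replicate 3. The medians of the xenobiotic, unfolded protein response, immediate early, junction, oxidative phosphorylation, ribosomal protein and histone lists also took both signs over the fits without 1 library. Median and mean log2 fold change differed in sign in 6 lists, of which 0 were called: the antimicrobial (mean 0.24), Wnt target (0.0043), immediate early (-0.02), senescence and p53 (-0.10), ribosomal protein (-0.02) and sex-linked (0.06) lists. Camera took the sign of the mean in the senescence and ribosomal protein lists and that of the median in the other 4. Single members of these lists that fell were Cox6b2, a cytochrome oxidase subunit (5.32 ± 0.616 to 1.81 ± 0.275 CPM, adjusted p = 0.00656), and Rps4l.

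**Figure D2:**
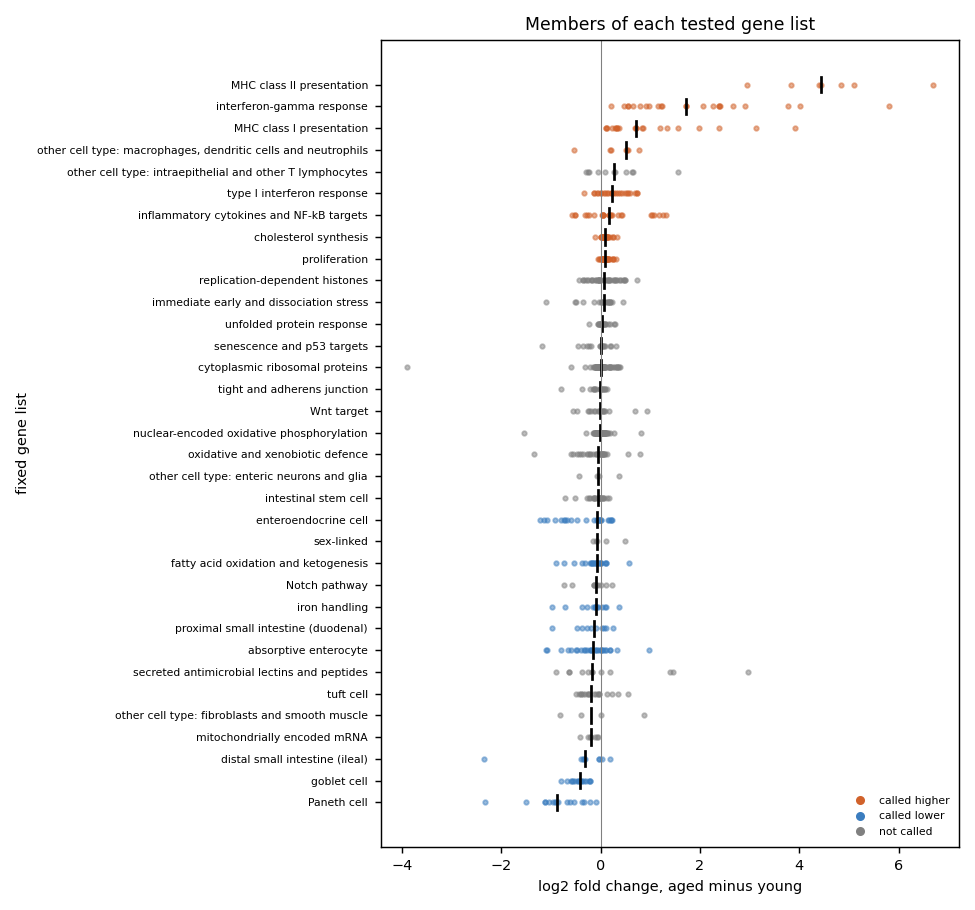
Log2 fold change (aged minus young) of every tested member of the 34 tested gene lists; points are genes, black ticks are list medians, and colour gives the camera call with the preset correlation. MHC class II presentation has the highest median (4.43) and the Paneth cell list the lowest (-0.88).

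Of the named genes Rps4l, a member of the ribosomal protein list, had the smallest adjusted p. This copy of a ribosomal protein gene, annotated as a transcribed processed pseudogene (ENSMUSG00000063171, chromosome 6, 148354656 to 148355598) fell from 74.2 ± 4.37 to 4.98 ± 0.294 CPM, a log2 fold change of -3.90 ± 0.09 (SE, adjusted p = 1.72e-07). Its reads can be shared with other copies. Outside the lists, Nrn1, a neuritin gene, fell by 2.71 on the log2 scale, AI467606 by 2.52, Arhgap4 by 1.88, the imprinted Peg3 by 1.81, Fkbp9 by 1.59, Trim35 by 1.49, Ptprn, which encodes a secretory granule protein, by 1.47, and Casc4 by 1.40 (adjusted p between 0.000298 and 0.0169). Among genes outside the lists that rose, P2rx7, an ATP-gated channel, went from 0.721 ± 0.194 to 9.99 ± 0.656 CPM (adjusted p = 0.000108), BC064078 rose 8.28-fold (adjusted p = 0.0176) and Gas7 rose 4.46-fold (adjusted p = 0.0067). P2rx7, Gas7, Rps4l, Nrn1, AI467606, Arhgap4, Fkbp9, Trim35 and Ptprn stayed past the threshold in all 6 fits without 1 library. Peg3 lost its call without young replicate 3 or aged replicate 2, and Casc4 and BC064078 in 4 fits each (adjusted p up to 0.059, 0.0814 and 0.153). A further 15 called genes had Gm, Rik or no symbols.

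**Figure D3:**
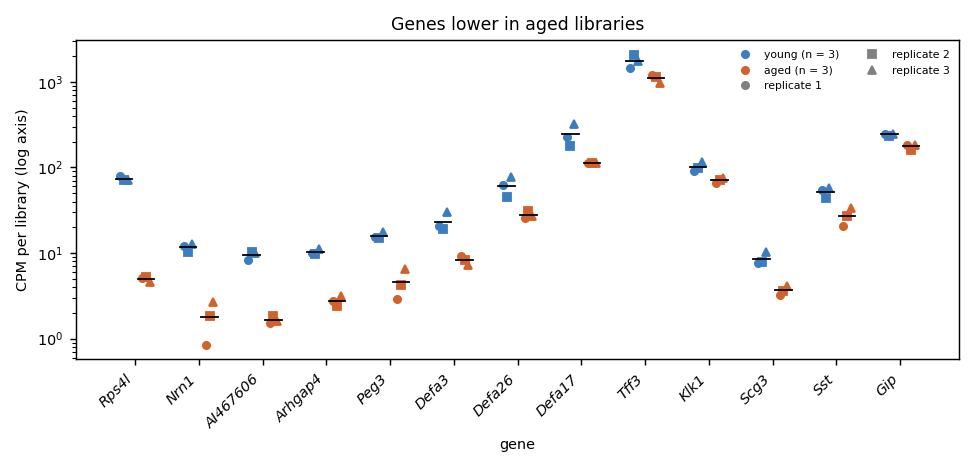
Scaled counts (CPM, log axis) of genes that fell in aged mice, per library; points are libraries and bars are group means. Rps4l went from a mean of 74.2 to 4.98 CPM, and Tff3 from 1755 to 1105 CPM.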

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

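The alternative without young replicate 2 and aged replicate 3 was chosen after seeing the data; the others were planned. Higher and lower gene counts were 206 and 276 with DESeq2, 168 and 245 with no filter, and 29 and 50 against a 1.5-fold threshold. With at least 1 CPM in 3 libraries, 67 genes were lower. Fits without 1 library gave 35 to 135 higher and 30 to 135 lower genes. Without both libraries that stood apart on the second component, 594 genes were higher and 587 lower; these libraries also lay closest to the other age on the first component, so their removal favours a larger contrast. Of the 93 and 117 genes, DESeq2 shared 92 and 117, and limma-voom 75 and 99. No called gene changed sign in the planned fits.

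With an estimated correlation, 0 lists were higher and 0 lower; fry gave 2 and 0, and 1 surrogate variable 3 and 5. Fits without 1 library gave 5 to 8 higher and 3 to 13 lower lists. The enterocyte median, -0.259 to 0.0272 over such fits, turned to 0.0213 without aged replicate 2, the fatty acid oxidation median to 0.0742 with 1 surrogate variable, and the unfolded protein response median to -0.128, there called lower. The cause of these changes was not tested. Fits without a library also had a smaller sample. RLE factors kept all 4 counts within 1.5 times, and upper-quartile factors, run for the gene counts only, kept both. Of 36 named genes called, 17 were called in all 6 fits without 1 library. What depth limits was not tested by subsampling; 103 of the 210 called genes averaged below 5 CPM.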

Other observations

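The tests on leukocyte transcripts and on crypt genes, the list of imprinted genes and 4 of the leukocyte transcripts were chosen after the results were seen; the other tests were set before their results, but how the segment and CpG tests were read was revised after their results were seen.

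Some called genes outside the fixed lists were singled out after their values were seen, and no enrichment of their functions was tested. Ly6e, a surface protein induced by interferons, rose from 191.2 ± 43.9 to 648.1 ± 50.3 CPM (edgeR adjusted p = 0.00248). Parp3 rose 3.32-fold, the receptor gene Tlr1 2.94-fold, Ifitm3, which restricts viral entry, 2.04-fold, Tmem173, which encodes STING, from 4.49 ± 0.370 to 9.64 ± 2.76 CPM, and Mlkl, the effector of necroptosis, 1.73-fold (adjusted p between 0.000685 and 0.0461). Ddr2, a collagen receptor, rose from 0.246 ± 0.0803 to 9.45 ± 1.04 CPM (adjusted p = 2.22e-05).

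Several low genes were close to undetected in aged libraries. Of the 117 lower genes, 14 had at most 3 counts in each aged library. Trpv6, an epithelial calcium channel, had 1.80 ± 0.479 CPM in young libraries and 0 counts in all 3 aged ones, at least 29.6-fold lower against a floor of 3 counts per library. The imprinted genes Meg3 (1.13 ± 0.176 to 0.0203 ± 0.00218 CPM), Dlk1 (0.497 ± 0.167 to 0.0919 ± 0.0309 CPM) and Rian (0.299 ± 0.0929 CPM to 0 counts) were called lower. Of 32 tested imprinted genes, 6 were called lower and Inpp5f higher (log2 fold change 0.74, adjusted p = 0.0412), with a median log2 fold change of -0.03. Camera in limma placed the list lower (unadjusted two-sided p = 0.00173, and p = 0.0268 with an estimated correlation), but the list was written once these calls had been seen, so neither p is independent evidence that imprinted genes fell as a class.

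Of the tested genes, 4 of 7 MHC class II and 13 of 23 interferon-gamma response genes rose in aged mice, with list adjusted p = 0.350 for both at an estimated correlation. Leukocytes passing the CD45-negative gate would bring their abundant transcripts. The macrophage list was called higher by camera with the preset correlation (median 0.51, adjusted p = 0.0189) but not with an estimated one (adjusted p = 0.350). Fry gave it an adjusted p of 0.0430, and Itgam and Itgae rose. Yet over 70 leukocyte transcripts, 9 of them above 1 CPM in young libraries, those with a higher mean in aged mice gained 28.1 ± 4.61 CPM in sum (SE). Itgam, Cd14, Ctss and Itgae gave 9.12, 8.70, 3.08 and 2.24 of it. The sum is 1.62% of the mean gain of Cd74 (1738 CPM), or 2.15% with 2 SE of the sum added. At these means this argues against leukocytes as the source of the class II transcripts. Neither share covers the spread of Cd74, which missed the threshold (edgeR adjusted p = 0.0593). Its aged libraries held 2186, 2555 and 663.8 CPM, so the share is larger for aged replicate 3. The same sum is 7.66% of the summed gain of the interferon-gamma response genes (366.3 CPM), which leaves leukocytes open there. Also open are a change with age in the epithelial cells, a hypothesis that was not tested, and differences between the mice, other than sex, that the labels do not give.

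Of the tested genes, 4 of 16 Paneth and 2 of 17 goblet genes fell in aged mice, with list adjusted p = 0.350 for both at an estimated correlation. If fewer crypt cells had been recovered, stem cell and proliferation genes would fall too, but their median log2 fold change was 0.037 ± 0.018 (bootstrap SE, 55 genes) against -0.88 for the Paneth list; the stem cell list alone reached -0.11 without young replicate 2. Reads shared among defensin copies do not account for the fall of the 9 Paneth genes outside that family, which had a median of -0.675 ± 0.169. Of the called Paneth genes only Mptx1 lies outside it (edgeR adjusted p = 0.0498). Shared reads thus stay open for the calls of Defa3, Defa26 and Defa17. Both bootstrap errors resample genes of the same 6 mice, which are not independent, and do not measure the spread between mice. Over the fits without 1 library the proliferation median ran from 0.01 to 0.18 and the Paneth median from -1.08 to -0.62. Unequal recovery of Paneth and goblet cells themselves, and their number or activity with age, stay open.

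The genes lower in aged mice lay on 19 chromosomes, with at most 13 on the same one. This argues against a single chromosome segment, differing between the animals, that holds all of them. Of these genes, 16 (13.7%, Wilson 95% interval 8.6 to 21.1) had a neighbouring tested gene that was also lower. Matched random lists had a median of 2 such genes, and the upper end of their central 95% was 6. A segment need not change every gene in it, so this count cannot show how many lower genes lie in segments. Segments that differed between the animals thus stay open, for those 16 and for other lower genes. As a hypothesis, CpG-rich transcript starts may mark the lower genes. The CpG observed/expected ratio of the first 500 bases had a median of 0.55 for the lower genes. That lay inside the central 95% of the medians of 10000 expression-matched random lists (0.446 to 0.559) but close to its upper end. The reading set before the result counted a median inside this range against the hypothesis. It was revised to undecided after the result was seen. The test thus gave the hypothesis no support, and a small excess of CpG is not excluded. The higher genes, looked at in the same way, had 0.38 (central 95% of random lists 0.474 to 0.589).

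The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split called 210 genes, and 1 of the 10 splits, the real one, called as many; the highest other, with young replicate 2 and aged replicate 3 exchanged, called 134. For lists called by camera with the preset correlation, 2 of the 10 splits gave as many, with 16 for the real split and 19 for the highest other. The other splits called 4, 11, 14, 19, 11, 13, 13, 11 and 11 lists. The count of 16 called lists thus does not stand apart from groupings that mix the ages. For the interferon-gamma list the smallest adjusted p of any other split was 3.47e-05 against 2.79e-31, for the Paneth list 3.73e-14 against 8.51e-15, and for the goblet list 3.74e-21 against 8.05e-12. A camera p as small as the real one came in 7 of the 10 splits, the real one included, for the fatty acid oxidation list. It came in 6 for the proliferation and absorptive enterocyte lists. It came in 3 for the type I interferon, NF-kB, enteroendocrine, cholesterol and duodenal lists, and in 2 for the goblet and ileal lists. Only the real split reached it for the MHC class I and II, interferon-gamma, Paneth, iron and macrophage lists.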
